A study of Mus musculus with 2 samples.

How the data were processed

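Single-cell RNA was measured in whole-lung suspensions of 2 male C57Bl/6J mice, each 4 months old, with 1 library per mouse. Per the labels' protocols, lungs were perfused through the right ventricle, digested with dispase and DNase, freed of red cells by lysis, and run on 10x Genomics 3' V2 chemistry. The series title concerns human lung and pulmonary fibrosis, and the 2 samples analysed here are both mouse samples of 1 group, "whole lung". Per the submitters' processing notes, reads were processed with bcl2fastq and Cell Ranger 1.3 against mm10; aligner settings are not stated in the labels. The deposited values are raw UMI counts per gene and cell barcode, and the authors' processing had already chosen the barcodes that count as cells. Each matrix came in 2 copies, which differed in 0 entries, and 1 of them was used.

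The deposited matrices held 27998 genes and 14518 barcodes. Mouse 1 had 6767 barcodes, 21914291 UMIs and a median of 2613 UMIs and 1121 genes per barcode, with 18049 genes detected and a median of 3.66% mitochondrial UMIs. Mouse 2 had 7751 barcodes, 19462644 UMIs and a median of 1820 UMIs and 800 genes, with 18056 genes detected and 3.57% mitochondrial. The lowest barcode held 1253 UMIs in mouse 1 and 822 in mouse 2, and 1825 kept cells of mouse 2 lay under 1253. Cells with fewer than 300 genes or at least 20% mitochondrial UMIs were removed (7 and 20), then Scrublet (in scanpy 1.11.5, expected rate 0.06, run per mouse) removed doublets (400 called, 5.91% of barcodes, and 331, 4.27%), leaving 6360 and 7400 cells.

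Counts were scaled per cell and log-transformed, and 2000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, seed 1) gave 32 clusters over both mice, with no batch correction. Clusters were named from 218 marker genes (211 in the gene table). Markers, 17 gene lists and the rule for naming genes were fixed before the data were examined, and the 455 listed genes (454 in the table, Clec7a is not) were left out of the clustering features so that the classes were not built on them. After the clusters were seen, 3 mixed clusters were divided with the clustering at resolution 2. Clusters with markers of more than 1 class, and 1 cluster of cycling cells, were left unnamed (167 cells in mouse 1, 109 in mouse 2). The cluster of conventional dendritic cells 1 (157 and 66 cells) kept its name although it also carried all 6 cycling markers. That class therefore includes cycling cells. For 65 repeated symbols, the gene ID with the most UMIs kept the symbol.

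Shares are given per mouse with exact Clopper-Pearson 95% intervals, and as mean and SD over n = 2. For tests, UMIs were summed per mouse and class for the 20 classes with at least 20 cells in each mouse (40 sums), and all sums entered 1 edgeR 4.0.16 fit (R 4.3.3) with TMM factors, filterByExpr and mouse as a block. The 2 classes of each comparison came from the same animals, which is where the pairing comes from. Genes were called by the quasi-likelihood test at a Benjamini-Hochberg FDR under 0.05 over 11536 genes; every adjusted p of a gene in the text is from this test unless DESeq2 is named. Standard errors of fold changes are on the log2 scale, levels are CPM (counts per 1e6 UMIs of the class sum) as mean ± SD over 2 mice, and the estimate of spread is shared by all 20 classes because 2 mice alone give too few degrees of freedom. Log2 differences within 1 mouse are of TMM-scaled log2 CPM with a prior count of 2. Where the lower class had 0 UMIs, the fold is given as a lower bound from a floor of 3 counts. Where it had 1 to 3 UMIs, the ratio is given with its exact Poisson counting interval. These bounds and ratios, like the CPM, leave out the TMM factors that fold changes use, so the sizes are not on 1 scale. The factors of mice 1 and 2 were 0.747 and 0.781 in AT2 cells and 1.25 and 1.36 in AT1 cells. In club cells Scgb1a1 alone took 549262 CPM, which lowers the CPM of other genes there. Levels and top classes are not TMM-scaled. The TMM factors ranged from 0.398 (club cells of mouse 1) to 1.63 (smooth muscle cells or pericytes of mouse 2). The order and distance of close classes can therefore differ on the scale of the fit.

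Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the 17 lists of a comparison. Named genes were, per comparison and direction, the 12 listed genes with the largest log2 fold change among those past the threshold, of the same sign in each mouse and with at least 20 UMIs in the higher class of each mouse; the 3 largest from outside lists, markers and clustering features under the same conditions; and the 2 members of smallest p of each list that passed camera. For the class where a listed gene is highest, each top class was compared with the mean of all other classes, which does not test it against the next class, and up to 4 genes per list with the highest level were eligible for naming, plus Wnt ligands with at least 20 UMIs, Axin2, Porcn and Wls. Differences between the mice were not tested; genes were listed by size, with at least 100 UMIs and a log2 ratio (offset 1 CPM) of at least 1 in at least 3 classes that had at least 100 cells in each mouse, and the 10 largest per direction were named. Coordinates are from GENCODE vM21 on mm10. Among 191 named genes, 6 shared over 20% of their 31-base words with another gene and 2 overlapped another gene on the same strand.

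The fit was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Counts were drawn with the fit's trend of spread over expression level, with no spread of single genes and no difference between mice. Changed genes held at least 100 UMIs in the 2 classes, so recovery and false calls may be less favourable for the genes tested in the data. It recovered 48 and 92 for alveolar against interstitial macrophages (11726 genes; 1.41% of calls false), 35 and 80 for AT2 against AT1 cells (11753; 7.26%), 59 and 97 for monocytes (11737; 1.27%) and 42 and 87 for endothelial cells against fibroblasts (11653; 0.769%). A gene that was not called may therefore still differ by 2-fold. RNA from other cells, estimated from Scgb1a1 (Sftpc in airway classes), made up 0.829 to 9.24% of a class's UMIs, with a median of 2.94%; it was not subtracted in the results reported.

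Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, the DESeq2 test, no low-count filter, no block, only the 2 compared classes in the fit, doublets kept, a stricter cell filter (500 genes, 10%), RNA from other cells subtracted, each mouse left out, resolutions 0.5 and 2, listed genes allowed in the clustering, and an estimated correlation for the lists. Chosen after the data were seen were an equal minimum of 1253 UMIs in both mice and a fit of only the classes with 50 cells in each mouse. Left out were lymphatic endothelial cells, mesothelial cells, basophils or mast cells and platelets from the fit, for having under 20 cells in a mouse, and the unnamed cells. Some genes that the naming rule picked are not reported here. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3, umap-learn 0.5.12 and matplotlib 3.10.9.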

Results

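Whole lungs of 2 male C57Bl/6J mice, 4 months old per the labels, gave 13760 cells after filtering: 6360 from mouse 1 and 7400 from mouse 2. From marker genes, 13484 of these cells were given 1 of 24 class names, and 276 cells in cycling or mixed clusters stayed unnamed. A class name here means that the cells carried the markers of that cell type (AT2-like, fibroblast-like and so on), since no cell was sorted or stained. The labels name no treatment and no disease for either mouse, and both mice belong to 1 group. The results below therefore compare cell classes within the lung, with the 2 mice as replicates. Kept cells held a median of 2524 UMIs and 1096 genes in mouse 1, and 1753 UMIs and 778 genes in mouse 2.

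B cells were the largest class of mouse 2 and AT2 cells the largest of mouse 1. B cells made up 12.4% (exact 95% interval 11.6 to 13.3) of the cells of mouse 1 and 33.3% (32.2 to 34.4) of mouse 2, with a mean of 22.9 and an SD of 14.8 (n = 2 mice). AT2 cells, which make surfactant, made up 19.7% (18.7 to 20.7) and 8.93% (8.29 to 9.61), with a mean of 14.3 and an SD of 7.58. Neutrophils differed most among the large classes, with 0.346% (0.217 to 0.523) in mouse 1 and 7.20% (6.62 to 7.82) in mouse 2. This 20.8-fold difference was 8.92-fold with an equal UMI minimum in both mice and 6.94-fold with the stricter cell filter, so its size depended on the choice of cells. T cells (15.4% and 12.2%), NK cells (4.26% and 6.34%) and non-classical monocytes (3.92% and 3.49%) differed less. Classical monocytes made up 1.87% (1.55 to 2.23) and 4.80% (4.32 to 5.31).

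Among the resident myeloid cells, alveolar macrophages made up 11.3% of mouse 1 and 7.05% of mouse 2, and interstitial macrophages 3.30% and 1.19%. Conventional dendritic cells 1 (2.47% and 0.892%, cycling cells among them) and 2 (2.72% and 0.730%) were also a larger share of mouse 1. Mature dendritic cells made up 0.472% and 0.270%, and plasmacytoid dendritic cells 0.362% and 0.541%. Innate lymphoid cells 2 made up 0.755% and 0.365%, basophils or mast cells 0.157% and 0.432%, and platelets 0.0943% and 0.338%.

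Endothelial cells were 9.58% of mouse 1 and 7.47% of mouse 2, fibroblasts 2.47% and 0.757%, and smooth muscle cells or pericytes 0.802% and 0.297%. AT1 cells, the flat cells of gas exchange, made up 2.25% and 0.703%, club cells 1.02% and 0.581%, and ciliated cells 1.32% and 0.446%. Lymphatic endothelial cells (0.220% and 0.0676%) and mesothelial cells (0.126% and 0.162%) were the rarest structural classes. By lineage, immune cells made up 59.8% and 78.8%, epithelial cells 24.2% and 10.7%, endothelial cells 9.80% and 7.54%, and mesenchymal cells 3.27% and 1.05%. These shares are of recovered cells after enzymatic digestion, and 2 mice of 1 group allow no test between them.

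**Figure D1:**
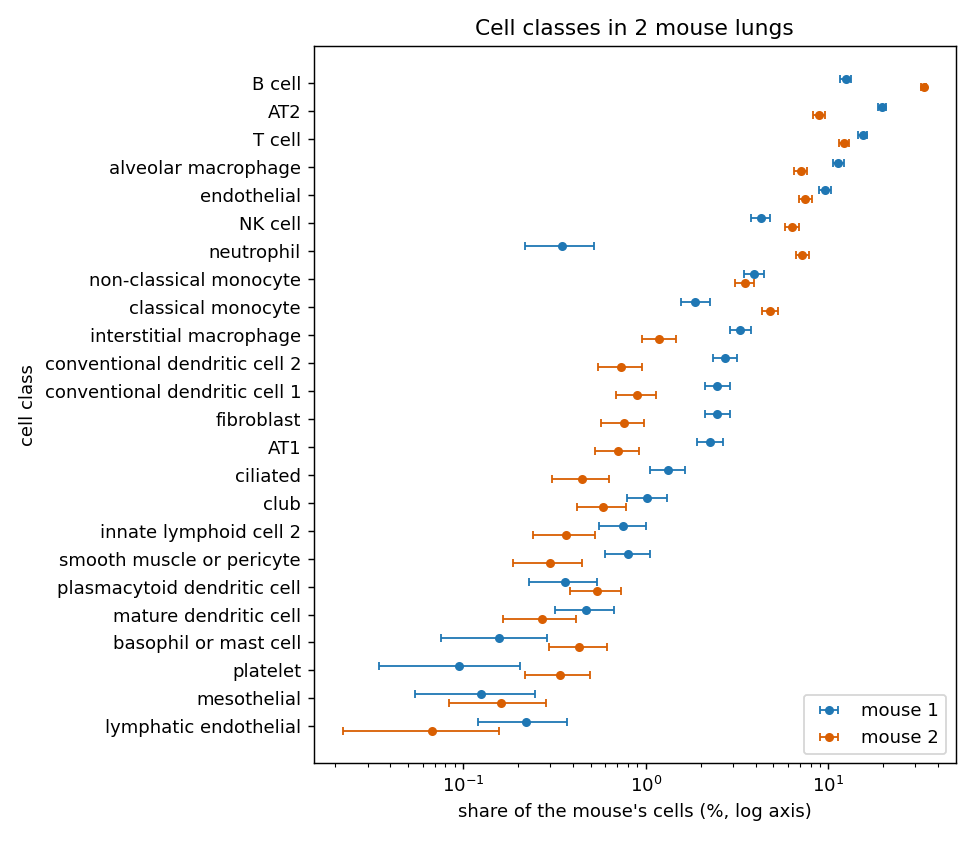
Share of cells (percent, log scale) of each named class in mouse 1 and mouse 2, with exact 95% intervals. Neutrophils (0.346% and 7.20%) lie farthest apart among the large classes.

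Alveolar and interstitial macrophages differed in chemokines, complement and lipid handling. Interstitial macrophages held far more of the chemokines Ccl8, Ccl12 and Cxcl13 and of the lipid carrier Apoe, and alveolar macrophages more of most genes for lipid uptake and storage. Of 11536 genes tested, 1449 were higher in alveolar and 1270 in interstitial macrophages (edgeR quasi-likelihood, Benjamini-Hochberg FDR < 0.05; 721 and 522 alveolar, 210 and 88 interstitial cells in mice 1 and 2). The 11536 genes include clustering features and markers, which had built and named the classes, so their calls were partly fixed in advance. Of the 10031 other genes, 1336 were higher in alveolar and 996 in interstitial macrophages. Of 409 listed genes tested, 74 were higher in alveolar and 119 in interstitial macrophages (77 and 128 when adjusted over the list alone). Across all calls, 2698 genes had the same sign in each mouse. With DESeq2 size factors the counts were 1377 and 1516, and with the DESeq2 test 1109 and 1397, so which class had more calls depended on the method.

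Of 28 chemokines and receptors tested, 1 was higher in alveolar macrophages, 16 in interstitial macrophages and 11 were not called (2 and 17 when adjusted over the list alone). The list's median log2 fold change was -2.22, with a camera adjusted p of 2.56e-10, which was 0.00419 with an estimated correlation. Ccl8, which attracts monocytes and T cells (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799), stood at 1188 ± 419 CPM (mean ± SD, n = 2) in interstitial macrophages, against 1 UMI in the alveolar macrophages of both mice together (ratio 5324, counting interval 954 to 210431). Other monocyte-attracting chemokines, Ccl12 (579 ± 76.2 CPM, ratio 817, 278 to 3975) and Ccl7 (207 ± 38.4 CPM, ratio 805, 143 to 31956), followed the same direction. So did the B cell attractant Cxcl13 (379 ± 87.6 CPM, ratio 1647, 294 to 65226) and the eosinophil attractant Ccl24 (104 ± 25.3 CPM, ratio 398, 69.8 to 15895). Ccl2, another monocyte attractant, was 105-fold higher (SE 0.50 in log2, adjusted p = 2.96e-22), and Cxcl16, a membrane-bound chemokine for T cells, 91.6-fold (SE 0.32, 3.25e-37).

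Lipid uptake, storage and efflux split between the 2 macrophages: 18 of 25 genes were higher in alveolar macrophages, 5 in interstitial macrophages and 2 were not called (median log2 1.3, camera adjusted p = 8.05e-06, and 0.0155 with an estimated correlation). Apoe, which carries lipid out of cells (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), was 362-fold higher in interstitial macrophages (SE 0.34, adjusted p = 9.83e-45), at 18988.5 ± 495 against 53.9 ± 17.7 CPM. In alveolar macrophages, the lipid droplet gene Cidec stood at 207 ± 19.4 CPM (ratio 103, counting interval 28.4 to 852), and the lipase Mgll was 28.6-fold higher (SE 0.38, 1.1e-21). The fatty acid carriers Fabp4 and Fabp5 were 21.5-fold (SE 0.41) and 13-fold (SE 0.37) higher there. The sterol exporter Abcg1 was 16.5-fold higher (SE 0.28, 1.69e-25; 1217 ± 161 against 75.7 ± 28.4 CPM) and the cholesterol ester hydrolase Nceh1 12.8-fold (SE 0.23, 1.85e-28). In cholesterol biosynthesis, 13 of 22 genes were higher in alveolar macrophages and 0 in interstitial macrophages. Among the 13 were the mevalonate pathway genes Mvd (9.31-fold) and Hmgcs1 (3.76-fold). The log2 differences of Mvd in the 2 mice lay 1.25 apart, the widest gap of the named genes in this comparison. The list's camera adjusted p of 0.000197 became 0.0918 with an estimated correlation. In the surfactant lipid list, 7 of 23 were higher in alveolar and 4 in interstitial macrophages (camera adjusted p = 0.488), with the fatty acid synthesis gene Acaca at least 4.50-fold higher in alveolar macrophages.

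Of 22 complement and Fc receptor genes, 3 were higher in alveolar and 13 in interstitial macrophages (median log2 -1.52, camera adjusted p = 1.32e-06, and 0.0426 with an estimated correlation). The complement receptor C3ar1 stood at 271 ± 83.3 CPM in interstitial macrophages (ratio 339, counting interval 115 to 1654). Of 16 MHC class II genes, 0 and 9 were called, led by H2-Eb1 (82.0-fold, SE 0.33) and H2-Ab1 (56.5-fold, SE 0.34; 7365 ± 1218 against 134 ± 3.21 CPM). The list's camera adjusted p was 1.07e-06, and 0.0740 with an estimated correlation. MHC class I genes (0 and 9 of 15; B2m 2.14-fold, Psmb9 2.38-fold higher in interstitial macrophages) had a camera adjusted p of 0.00909, and 0.175 with an estimated correlation. Interferon response genes (1 and 11 of 24; Ifitm2 19.8-fold, Ifi27l2a 12.9-fold) had 0.000470, and 0.175 with an estimated correlation.

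Lysosome, immediate early and matrix genes passed camera only with the preset correlation. Lysosome and phagocytosis genes (6 and 12 of 26, 0.00909, and 0.249 with an estimated correlation) included the protease Ctsk, at 190 ± 54.0 CPM in alveolar macrophages (ratio 90.6, counting interval 25 to 750). On the interstitial side of that list, the lectin Cd209f was at least 409-fold higher. Immediate early and heat shock genes (4 and 13 of 26, 0.0120, and 0.361 with an estimated correlation) included Egr2 (10.3-fold) and Klf4 (5.24-fold) on the alveolar and Ier3 (7.76-fold) on the interstitial side. In the extracellular matrix list (1 and 7 of 45, 0.0287, and 0.249 with an estimated correlation), the elastase Mmp12 was 31.6-fold and Timp2 5.33-fold higher in interstitial macrophages. Growth factors and receptors (4 and 10 of 38, camera adjusted p = 0.0554) held Spp1 (25.4-fold) and Flt1 (23.8-fold) on the alveolar and the phagocytosis bridge Gas6 (92.0-fold) on the interstitial side. The other lists gave 0 and 0 of 11 Wnt ligands, 1 and 1 of 17 Wnt receptors, 4 and 3 of 28 TGF-beta, 2 and 4 of 15 senescence (Ccnd2 9.97-fold higher in alveolar macrophages) and 9 and 2 of 28 oxidant genes. Outside the lists, the channel Mcoln3 (at least 37.2-fold), the fatty acid receptor Ffar2 (at least 16.5-fold) and the flippase Atp10a (at least 12.9-fold) were higher in alveolar macrophages. Gas7 (ratio 257, counting interval 69.7 to 2148), Pdlim4 (228, 61.7 to 1908) and Serpinf1 (270, 46.7 to 10815) were higher in interstitial macrophages. Of these genes, 10 kept their sign but were not called by DESeq2: Ffar2, Cidec, Ccl2, Ccl7, Ccl8, Ccl12, Ccl24, Cxcl13, C3ar1 and Cd209f (adjusted p 0.0658 to 0.661; at most 5.28e-05 in every other setting). Cd209f also shares sequence with Cd209g, so its counts are uncertain.

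AT2 and AT1 cells differed in surfactant lipid and cholesterol synthesis on the AT2 side and in matrix and Wnt ligand genes on the AT1 side. The desaturase Scd1 was 310-fold higher in AT2 cells, with a size that differed between the mice, and the vascular growth factor Vegfa 38.7-fold higher in AT1 cells. Of 11536 genes, 1848 were higher in AT2 and 1285 in AT1 cells (edgeR, 1250 and 661 AT2 cells, 143 and 52 AT1 cells in mice 1 and 2), and 3113 of these had the same sign in each mouse. With DESeq2 size factors in place of TMM the counts were 1506 and 1710, so the balance of the 2 directions depended on the normalization. Of the 10031 genes that were neither clustering features nor markers, 1711 were higher in AT2 and 1035 in AT1 cells. Of 409 listed genes, 98 were higher in AT2 and 74 in AT1 cells (100 and 76 when adjusted over the list alone).

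Of 23 surfactant lipid genes, 17 were higher in AT2 cells, 2 in AT1 cells and 4 were not called (median log2 3.43, camera adjusted p = 2.92e-11, and 0.0140 with an estimated correlation). Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879) stood at 3776 ± 674 CPM in AT2 and 29 ± 34.3 CPM in AT1 cells (SE 0.39, adjusted p = 3.99e-38). The AT1 level came from 2 UMIs in mouse 1 and 9 in mouse 2, and the log2 difference was 9.43 in mouse 1 and 7.03 in mouse 2. Fabp5 was 195-fold higher (SE 0.50), Lgi3 50.8-fold (SE 0.30, 3.43e-34), and the transcription factor Etv5, which maintains AT2 identity, stood at 463 ± 70.0 CPM (ratio 265, counting interval 47.4 to 10453). Of 22 cholesterol genes, 18 were higher in AT2 and 1 in AT1 cells (median log2 2.69, camera adjusted p = 8.83e-09, and 0.0140 with an estimated correlation). They included the mevalonate pathway gene Pmvk (10.4-fold, SE 0.28). Lipid uptake genes were split 10 and 5 of 25 (camera adjusted p = 0.0969), with Cd36 190-fold higher in AT2 cells (log2 7.57, SE 0.42, but log2 12.61 with RNA from other cells subtracted, so its size is uncertain), Apoc1 at a ratio of 89.6 (30.6 to 435) and the sterol sensor Nr1h3 at least 4.23-fold higher. MHC class II genes were split 8 and 0 of 16 (camera adjusted p = 0.114).

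Growth factors differed by member. The bone morphogenetic proteins Bmp3 (at least 6.04-fold), Bmp5 (at least 4.61-fold) and Bmp2 (at least 3.90-fold), the EGF receptor ligand Areg (at least 9.65-fold) and the macrophage growth factor Il34 (at least 3.58-fold) were higher in AT2 cells. AT1 cells held more Tgfb2 (145-fold, SE 0.51, 2.2e-24; 169 ± 37.6 against 0.607 ± 0.262 CPM), the TGF-beta-activating integrin subunit Itgb6 (32.4-fold, SE 0.30) and Ctgf (132-fold, SE 0.51). Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369) stood at 2506 ± 491 against 38.1 ± 8.88 CPM (SE 0.24, adjusted p = 4.01e-39), and Igf1r was 32.6-fold higher in AT1 cells. Over the whole lists, growth factors (6 and 9 of 38) and TGF-beta genes (5 and 6 of 28) did not pass camera (0.120 and 0.328).

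Of 11 Wnt ligand and secretion genes tested, 0 were higher in AT2 and 4 in AT1 cells (median log2 -1.36, camera adjusted p = 0.00154, and 0.0271 with an estimated correlation). Wnt7a was 47.9-fold (SE 0.69, 3.2e-11; 63.4 ± 36 against 0.514 ± 0.167 CPM, with 37.9 against 0.632 CPM in mouse 1 and 88.8 against 0.396 in mouse 2, from 4 AT2 UMIs in all) and Wnt3a 11.6-fold higher (SE 0.46, 1.96e-10; 81.7 ± 18.4 against 3.97 ± 0.548 CPM). Of 45 matrix genes, 2 were higher in AT2 and 16 in AT1 cells (camera adjusted p = 8.59e-06, and 0.0296 with an estimated correlation). The list's fitted median was 0.02 and its mean -0.38, of unlike sign, and its median with bounds for genes absent from 1 class was -2.19. The elastic fibre gene Fbln5 (82.2-fold, SE 0.23, 1.57e-47), the basement membrane genes Col4a3 (28.3-fold, SE 0.17, 3.73e-49) and Lama3 (25.4-fold, SE 0.32) were among the 16. Interferon response genes were split 1 and 5 of 24 (camera adjusted p = 0.0321, and 0.446 with an estimated correlation), with Ifit3 (19.2-fold) and Xaf1 (7.85-fold) higher in AT1 cells. Ifit3 shares sequence with Ifit3b, which makes its counts uncertain.

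AT1 cells also held more of the stress gene Ier3 (47.1-fold, SE 0.26; 1742 ± 43.4 CPM), the cell cycle inhibitor Cdkn2b (30.2-fold, SE 0.22), Cyp4b1 (59.5-fold, SE 0.28) and Gsto1 (24-fold, SE 0.33). The lists these belong to did not pass: immediate early 5 and 5 of 26, senescence 3 and 4 of 15, oxidant 8 and 6 of 28. Nor did Wnt receptors (5 and 2 of 17), chemokines (0 and 2 of 28), MHC class I (1 and 1 of 15), complement (4 and 2 of 22) or lysosome genes (5 and 4 of 26). Outside the lists, the carboxypeptidase Cpm (at least 78.5-fold), Egfl6 (at least 60.5-fold) and the mucin Muc1 (at least 52.9-fold) were higher in AT2 cells. The nucleotidase Nt5e (133-fold), Rasgrf2 (122-fold) and Popdc3 (ratio 307, counting interval 101 to 1525) were higher in AT1 cells. DESeq2 did not call 6 of the named genes, which kept their sign: Areg 0.546, Bmp2 0.0598, Il34 0.606, Wnt3a 0.860, Wnt7a 0.720 and Popdc3 0.354 as adjusted p, against at most 0.000391 in the other settings with a value (6 for Il34, 9 for the rest).

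Classical and non-classical monocytes, which both circulate in blood and collect in lung vessels, differed less than the other pairs. Non-classical monocytes held far more Fabp4 and Pparg, and classical monocytes more Capg, Clec4a2 and Cfp. Of 11536 genes, 460 were higher in classical and 506 in non-classical monocytes (edgeR, 119 and 355 classical, 249 and 258 non-classical cells in mice 1 and 2), and 951 of these had the same sign in each mouse. The balance turned in some settings (657 and 515 with the stricter cell filter, 638 and 521 with doublets kept, 550 and 402 with no low-count filter, 805 and 579 with only classes of 50 cells), and without the mouse block the counts were 254 and 328. Of the 10031 genes that were neither clustering features nor markers, 384 were higher in classical and 371 in non-classical monocytes. Of 409 listed genes, 34 were higher in classical and 43 in non-classical monocytes (42 and 62 when adjusted over the list alone).

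Fabp4, a fatty acid carrier (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576), was 46.0-fold higher in non-classical monocytes (SE 0.32, adjusted p = 5.71e-29; 308 ± 43.8 against 4.84 ± 2.86 CPM). The tetraspanin Cd9 (14.9-fold, SE 0.38), the lipid-sensing receptor Pparg (13.8-fold, SE 0.42), the fatty acid receptor Cd36 (8.86-fold, SE 0.32) and Pltp (4.10-fold, SE 0.35) moved the same way, as did the phosphatase Acp5 (3.71-fold, SE 0.34). On the classical side, the sterol carrier Npc2 was 2.91-fold (SE 0.22, 1.49e-08) and the lipase Lpl 2.77-fold higher (SE 0.44, 0.0207). The log2 differences of Lpl in the 2 mice lay 1.83 apart, the widest gap of the named genes in this comparison. The lipid uptake list was split 3 and 6 of 25 and did not pass camera (0.204), and its members moved both ways.

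Of 24 interferon response genes, 8 were higher in classical and 1 in non-classical monocytes (12 and 1 when adjusted over the list alone), with a camera adjusted p of 2.59e-05, and 0.173 with an estimated correlation. Ifit1 was 8.28-fold (SE 0.69, 0.000765) and Isg15 3.77-fold higher (SE 0.35, 1.88e-05). Lysosome genes were split 6 and 1 of 26 (10 and 1 when adjusted over the list alone; 0.00165), with Ctsc 3.25-fold (SE 0.24), Trem2 2.60-fold and Hexa 2.30-fold higher in classical monocytes. TGF-beta genes (0 and 5 of 28, 0.00296), cholesterol genes (2 and 4 of 22, 0.00296), matrix genes (0 and 5 of 45, 0.00296) and growth factors (0 and 6 of 38, 0.0144) leaned to non-classical monocytes. All 6 of these lists had an adjusted p = 0.173 with an estimated correlation, so no list result of this comparison held.

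Named members higher in non-classical monocytes were Vegfa (ratio 17.8, counting interval 4.34 to 156), Pdgfb (10.9-fold), the TGF-beta receptor Tgfbr1 (3.34-fold, SE 0.29) and the integrin Itgav (3.93-fold, SE 0.35). Matrix genes among them were Timp3 (5.22-fold), Mgp (3.71-fold) and Sparc (3.52-fold), and cholesterol genes were Hmgcs1 (4.13-fold) and the regulator Srebf2 (2.45-fold). The AT1 markers Ager (189 ± 87.4 against 33.5 ± 12.4 CPM) and Cldn18 (92.1 ± 68.5 against 27.3 ± 25 CPM), named here after their values were seen, were also higher in non-classical than in classical monocytes. Vegfa and Sparc were highest in AT1 cells and Mgp and Timp3 in fibroblasts, so whether monocytes made these 4 transcripts is uncertain. Each kept its call with RNA from other cells subtracted. That subtraction was scaled to the club transcript Scgb1a1, so it cannot exclude RNA from AT1 cells or fibroblasts. The same doubt holds for Cd9, highest in alveolar macrophages and then AT1 cells. It also holds for Cd36 and Pdgfb, which were higher in endothelial cells than in fibroblasts. The Fc receptor Fcgr4 (7.67-fold, SE 0.24, 6.96e-19), the MHC class I gene H2-Q7 (7.80-fold, SE 0.45), the cyclin Ccnd2 (7.0-fold, SE 0.40) and the transcription factor Klf4 (3.56-fold, SE 0.26) were also higher there. Classical monocytes held more of the complement genes Cfp (5.43-fold, SE 0.31) and C3 (2.51-fold), the class II pathway genes Ifi30 (3.84-fold, SE 0.26), H2-DMa (2.71-fold) and H2-DMb1 (2.35-fold), the chemokine Ccl9 (3.61-fold; 703 ± 4.72 against 209 ± 54.5 CPM) and Fos (3.17-fold).

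The lists that did not pass were MHC class II (3 and 0 of 16, camera adjusted p = 0.0575), MHC class I (0 and 2 of 15), complement (5 and 2 of 22), immediate early (3 and 4 of 26), chemokines (2 and 2 of 28), senescence (1 and 2 of 15), surfactant (1 and 1 of 23), oxidant (0 and 1 of 28), Wnt receptors (0 and 1 of 17) and Wnt ligands (0 and 0 of 11). Outside the lists, the actin-capping gene Capg (11.2-fold, SE 0.31, 1.63e-17), the lectin Clec4a2 (6.37-fold) and Mnda (6.07-fold) were higher in classical monocytes. The ion transporter Slc12a2 (30.5-fold), the phosphatase Dusp16 (27.1-fold) and Lilra5 (ratio 26.5, counting interval 8.54 to 133) were higher in non-classical monocytes. DESeq2 did not call Lpl (0.0701), H2-DMa (0.146), H2-DMb1 (0.0667) or Fcgr4 (0.592), which kept their sign, against at most 0.0491 in the other settings, except that Lpl was also not called without the mouse block (0.0630). H2-DMb1, H2-Q7 and Mnda share sequence with related genes and are uncertain at the level of the single gene.

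Endothelial cells and fibroblasts differed most in matrix genes, which were higher in fibroblasts. Of 11536 genes, 1354 were higher in endothelial cells and 1426 in fibroblasts (edgeR, 609 and 553 endothelial cells, 157 and 56 fibroblasts in mice 1 and 2), and 2728 of these had the same sign in each mouse. The balance of directions depended on the method here too (935 and 1468 with the DESeq2 test, 1505 and 1365 with no low-count filter). Of the 10031 genes that were neither clustering features nor markers, 893 were higher in endothelial cells and 1108 in fibroblasts. Of 409 listed genes, 70 were higher in endothelial cells and 134 in fibroblasts (76 and 144 when adjusted over the list alone).

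Of 45 matrix genes, 1 was higher in endothelial cells, 32 in fibroblasts and 12 were not called (3 and 37 when adjusted over the list alone), with a median log2 of -3.58 and a camera adjusted p of 2.51e-25, which was 0.000426 with an estimated correlation. Collagen I, Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), was 347-fold higher in fibroblasts (SE 0.28, adjusted p = 1.5e-50; 1019 ± 148 against 3.07 ± 1.94 CPM). Col6a3 was 212-fold higher (SE 0.45), and Col6a2 (ratio 197, counting interval 53.2 to 1655) and Col13a1 (365, 63.8 to 14591) went the same way. The cross-linking enzymes Loxl1 (ratio 444, 121 to 3689) and Lox (265, 72.0 to 2216), Fbln1 (338, 91.9 to 2812) and the basement membrane ligand Npnt (108-fold, SE 0.31, 4.31e-39) were also higher in fibroblasts.

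Endothelial cells held more of the vascular growth factor receptors Kdr (1721 ± 107 CPM, ratio 423, counting interval 117 to 3493), Flt1 (547 ± 59.8 CPM, ratio 88.1, 30.1 to 428) and Flt4 (65.1 ± 5.41 CPM, ratio 31.6, 5.57 to 1255). Pdgfb, which recruits pericytes, stood at 278 ± 39.1 CPM (ratio 45.8, 15.6 to 223). In fibroblasts, Igf1 stood at 260 ± 19.7 CPM (ratio 176, 58.7 to 863), and Igfbp5 was 35.7-fold higher (SE 0.29). Over 38 growth factor genes, 10 and 15 were called (camera adjusted p = 0.0194, and 0.178 with an estimated correlation). TGF-beta genes were split 8 and 12 of 28 (0.0566), with the BMP inhibitor Smad6 higher in endothelial cells (402 ± 60.5 CPM, ratio 96.8, 26.7 to 800). Wnt receptors were split 5 and 8 of 17 (0.0975), with the Wnt inhibitor Nkd1 23.4-fold (SE 0.35, 4.06e-22; 683 ± 124 CPM) and Fzd6 at least 5.18-fold higher in endothelial cells. Wnt ligands were split 1 and 4 of 11 (0.0565).

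MHC class I genes were split 13 and 0 of 15 (camera adjusted p = 4.79e-05, and 0.105 with an estimated correlation), with H2-Q7 13.8-fold (SE 0.47) and H2-D1 4.87-fold higher in endothelial cells (SE 0.25; 2320 ± 330 against 457 ± 117 CPM). The senescence and arrest list (6 and 1 of 15, 0.0263) holds cyclins as well as cell cycle inhibitors, so its calls are not all of arrest genes. Higher in endothelial cells were the inhibitor Cdkn1a (12.4-fold, SE 0.30) and the cyclin Ccnd1 (14.4-fold, SE 0.41, but log2 5.95 in mouse 1 and 1.82 in mouse 2). Complement genes (1 and 6 of 22, 0.0118) included C3 (ratio 214, counting interval 71.8 to 1048) and C4b (238, 64.3 to 1988), both higher in fibroblasts, but the list's median log2 was 0.445 in mouse 1 and -1.02 in mouse 2, so its direction differed between the mice. Oxidant and xenobiotic genes (1 and 11 of 28, 0.00780) included Sod3 (277-fold, SE 0.26, 4.38e-53) and Gpx3 (51.5-fold, SE 0.28; 5066 ± 1420 CPM) in fibroblasts and Cyp4b1 (ratio 209, 71.4 to 1013) in endothelial cells. The senescence, complement and oxidant lists each had an adjusted p = 0.178 with an estimated correlation, so the matrix result alone held.

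The chemokine list (2 and 3 of 28, camera adjusted p = 0.766) contained opposite extremes: Cx3cl1, which tethers monocytes, was at least 19.7-fold higher in endothelial cells and Cxcl14 155-fold higher in fibroblasts (SE 0.25; 986 ± 213 CPM). Other lists that did not pass were lipid uptake (7 and 6 of 25; Cd36 61.3-fold higher in endothelial cells, SE 0.34), surfactant (3 and 6 of 23), cholesterol (0 and 4 of 22), MHC class II (0 and 6 of 16), lysosome (1 and 9 of 26), immediate early (6 and 9 of 26) and interferon genes (5 and 2 of 24). Gbp4 of the interferon list was higher in endothelial cells (ratio 37.4, counting interval 6.62 to 1488), though it overlaps Gbp8 and Gbp9 on the same strand and is uncertain. Outside the lists, Map3k11 (at least 16.2-fold), Fry (at least 14-fold) and Epha2 (at least 10.2-fold) were higher in endothelial cells. Fibroblasts held more of the glutamate transporter Slc1a3 (ratio 497, counting interval 87.5 to 19791), Lrp1 (106-fold) and Scarf2 (91.8-fold). Flt4 (0.388), Igf1 (0.117), Lox (0.308) and Col13a1 (0.28) kept their sign but were not called by DESeq2, against adjusted p of at most 0.000115 in every other setting.

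**Figure D2:**
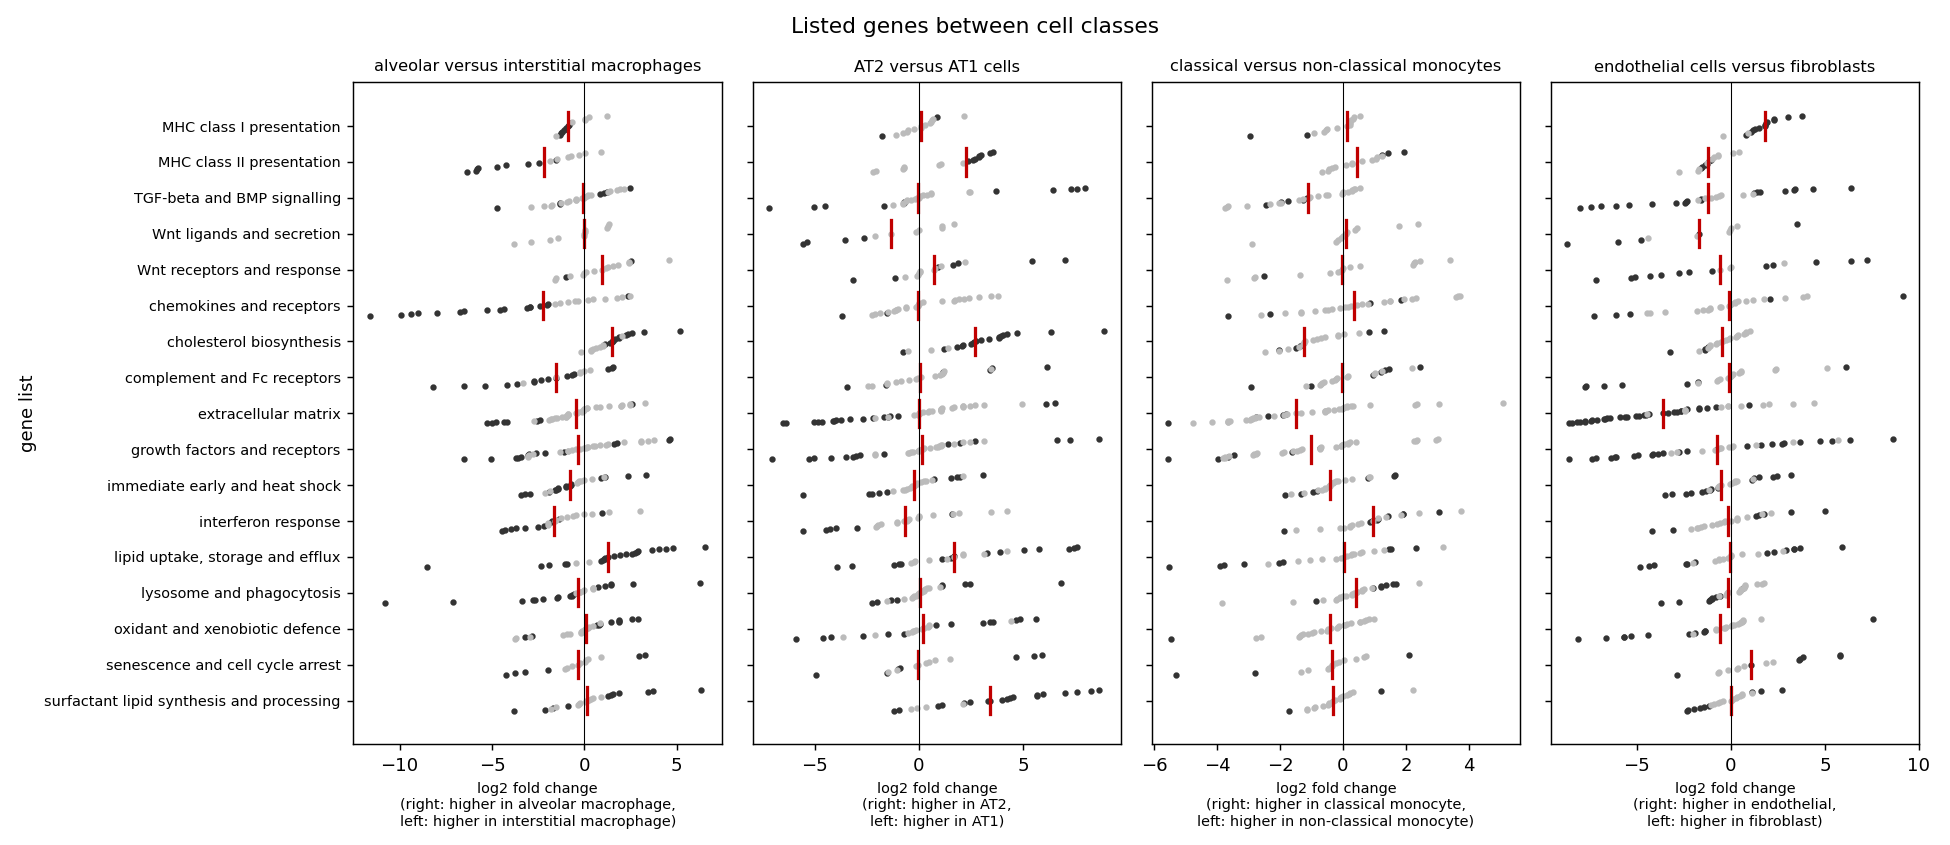
Log2 fold change of each listed gene by list (vertical axis) in the 4 class comparisons; black points passed FDR 0.05, grey points did not, and red bars mark list medians. Matrix genes lie on the fibroblast side (median -3.58) and surfactant genes on the AT2 side (median 3.43).

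The fry test, which asks whether the genes of a list move 1 way and does not compare them with other genes, gave an adjusted p of 1.03e-13 for chemokines in the macrophages, 3.50e-13 for surfactant genes in AT2 and AT1 cells, 0.00319 for interferon genes in monocytes and 1.14e-15 for matrix genes in endothelial cells and fibroblasts. It also passed lists that camera did not, such as Wnt ligands in macrophages (0.00919) and in endothelial cells and fibroblasts (3.44e-08). Median, mean and test of a list were of unlike sign for oxidant genes in the macrophages, and for growth factors, TGF-beta, chemokines, MHC class I, complement, senescence and oxidant genes in AT2 and AT1 cells. The same held for lipid uptake, MHC class I and complement genes in monocytes and for lipid uptake and interferon genes in endothelial cells and fibroblasts. None of these lists passed camera; the matrix list in AT2 and AT1 cells, given above, was of unlike sign and did pass.

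Each listed gene was also placed in the class, of 20 with enough cells, where its level was highest. For 305 of 409 listed genes tested, the same class was on top in each mouse. The top class was chosen and compared with the mean of the other classes on the same values, so the 402 genes past FDR 0.05 in that comparison (303 with the same top class in each mouse) do not show that the top class exceeded the next. Counted by list over these 303 genes alone, matrix genes were most often highest in fibroblasts (23 of 38) and AT1 cells (10), surfactant genes in AT2 cells (13 of 19) and AT1 cells (5), and lipid uptake genes in alveolar macrophages (7 of 18). Growth factors were highest in endothelial cells (8 of 33), fibroblasts (7) and AT1 cells (5), TGF-beta genes in endothelial cells and fibroblasts (7 each of 21), and chemokines in interstitial macrophages (7 of 21) and NK cells (4). Cholesterol genes were most often highest in mature dendritic cells (8 of 12), with Pmvk at 303 ± 91.4 and Idi1 at 264 ± 35.6 CPM.

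Wnt ligands differed in their source. Wnt3a (81.7 ± 18.4 CPM, ENSMUSG00000009900, chromosome 11, 59248033 to 59290752), Wnt7a (63.4 ± 36) and the Wnt export gene Wls (359 ± 14.4, with AT2 cells next at 196) were highest in AT1 cells. Wnt2 was highest in fibroblasts (99.7 ± 8.56 CPM, next endothelial cells at 1.28), as was Wnt5a (81.1 ± 2.58), although smooth muscle cells or pericytes were higher in mouse 2 (mean 69.7). Ciliated cells held the highest Wnt4 (145 ± 6.95), Wnt11 (78.7 ± 5.32) and Porcn (158 ± 11.5), which readies Wnt proteins for release. The Wnt target Axin2 was highest in fibroblasts (54.5 ± 4.37 CPM, from 18 and 8 UMIs), followed by innate lymphoid cells 2 (35.5) and smooth muscle cells or pericytes (26). Nkd1, another Wnt target, stood at 683 ± 124 CPM in endothelial cells, where Fzd4 (156 ± 2.10) was also highest, while Fzd2 was highest in AT1 cells (140 ± 20) and Dkk3 in fibroblasts (164 ± 13.1). Wnt9a had another top class in each mouse, Wnt6 and Wnt7b were below the count filter, and Wnt1, Wnt8a and Rspo4 had 0 UMIs.

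**Figure D3:**
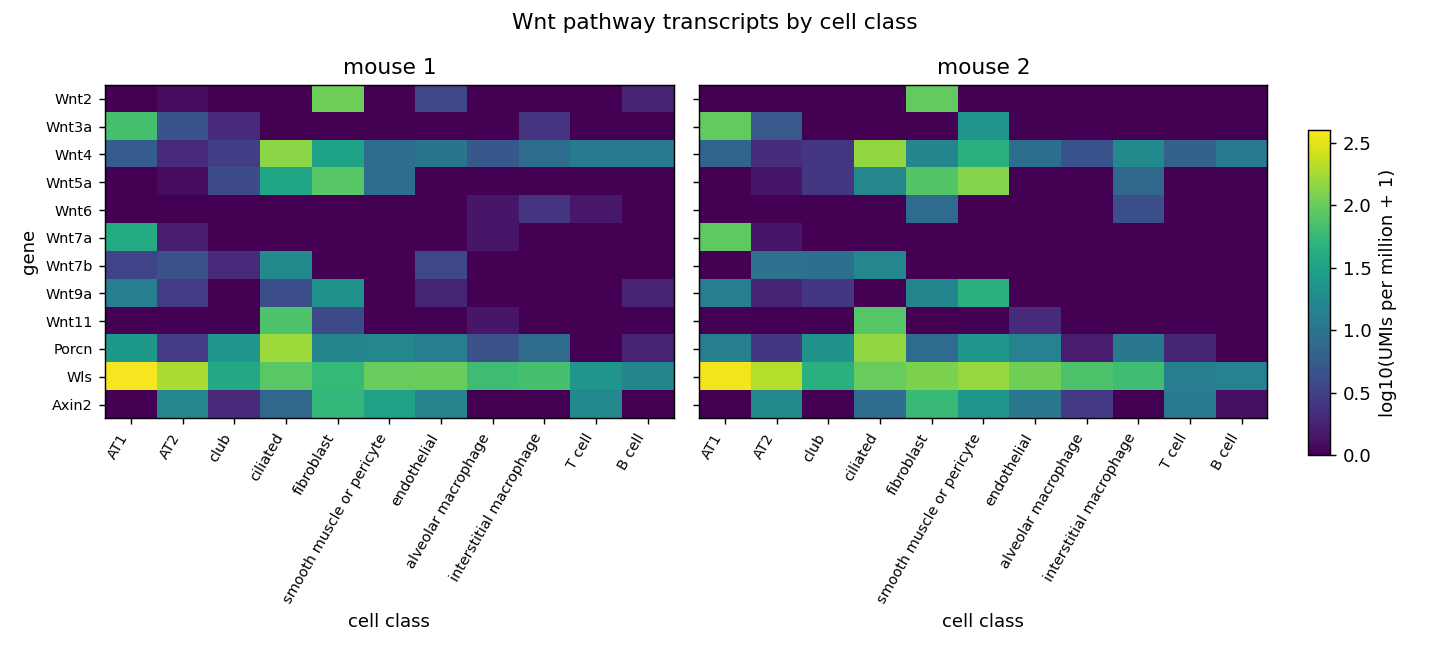
Level of Wnt ligands, Porcn, Wls and Axin2 (vertical axis) in 11 cell classes (horizontal axis), as colour on a scale of log10 of CPM plus 1, with 1 panel per mouse. Wnt3a (mean 81.7 CPM) and Wnt7a (63.4 CPM) stand out in AT1 cells and Wnt2 (99.7 CPM) in fibroblasts.

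Other listed genes are given with the class where they were highest, which for several was not far above the next. AT1 cells were highest in Vegfa (2506 ± 491 CPM) and Pdgfa (1068 ± 87.5), while endothelial cells were highest in the Vegfa receptors Kdr (1721 ± 107) and Nrp1 (1943 ± 5.71). Endothelial cells also led for the BMP pathway genes Acvrl1 (1149 ± 37.9), Eng (973 ± 119), Id1 (1140 ± 121) and Id3 (1802 ± 224, with smooth muscle cells or pericytes next at 1174), and for Jun (1498 ± 72.9). Fibroblasts led for Mgp (13698 ± 1245) and Bgn (1759 ± 144, next smooth muscle cells or pericytes at 965), smooth muscle cells or pericytes for Eln (2217 ± 3.84), and AT1 cells for Sparc (3921 ± 250, next fibroblasts at 1816) and Prdx6 (5012 ± 1018). Ccl5 was highest in NK cells (26977 ± 1938), Ccl6 in alveolar macrophages (3531 ± 407, next neutrophils at 2020) and Ccl22 in mature dendritic cells (1365 ± 723). H2-Aa was highest in conventional dendritic cells 2 (7471 ± 655), with interstitial macrophages (6700) and conventional dendritic cells 1 (5989) close. H2-DMb2 was highest in B cells (989 ± 1.57), though it shares sequence with H2-DMb1 and its counts are uncertain, and H2-K1 in NK cells (2229 ± 86.6, next innate lymphoid cells 2 at 1900). Ifitm3 was highest in classical monocytes (5091 ± 1214, next non-classical monocytes at 3667) and Ifitm1 in neutrophils (3329 ± 3670), the latter at 734 CPM in mouse 1 and 5924 in mouse 2. Ctsd (2171 ± 119) and Cd9 (2093 ± 282, next AT1 cells at 1105) were highest in alveolar macrophages. Fcer1g (3355 ± 31.9, next NK cells at 2799) and Gpx1 (3031 ± 192, next classical monocytes at 2055) were highest in non-classical monocytes, and Mt1 (2426 ± 208, next alveolar macrophages at 1259) and Hsp90aa1 (2688 ± 1119) in ciliated cells.

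Between the 2 mice, levels of a class's genes correlated closely, and many of the genes that differed most were near copies of ribosomal or other abundant genes. Across genes, log2 CPM of the 2 mice correlated at r = 0.979 in AT2 cells, 0.978 in alveolar macrophages and 0.949 in classical monocytes, the lowest of 8 classes. By a size rule (at least 100 UMIs and a 2-fold difference in at least 3 classes), 45 genes differed, and with 1 library against 1 these are values without a test. Cldn18 (median log2 ratio of mouse 2 to mouse 1 -1.3) and Sparc (-0.83), an AT1 marker and an AT1-rich gene, were higher in mouse 1 in 3 classes each. For Cldn18 these were B cells (38.4 and 14.2 CPM in mice 1 and 2), T cells (39.8 and 12.3) and alveolar macrophages (32.5 and 13.4), while in AT2 cells its level was 707 and 674 CPM. The other 43 were higher in mouse 2, led by Rpl13a-ps1 (2.95), Gm10250 (2.67), Gm10260 (2.51), Rpl7a-ps5 (2.47), Gm10020 (2.38), Rpl10-ps3 (2.37), the neutrophil gene Retnlg (2.37), Gm10116 (2.35), Gm10269 (2.32) and Lrrc58 (2.30). In AT2 cells, Rpl10-ps3 stood at 288 CPM (Poisson interval 273 to 304) in mouse 1 and 1537 (1489 to 1587) in mouse 2, and in endothelial cells at 106 (88.5 to 127) and 537 (490 to 587). The neutrophil genes S100a9 (2.16) and S100a8 (1.88), named here after their values were seen, also passed the rule, in classes other than neutrophils.

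**Figure D4:**
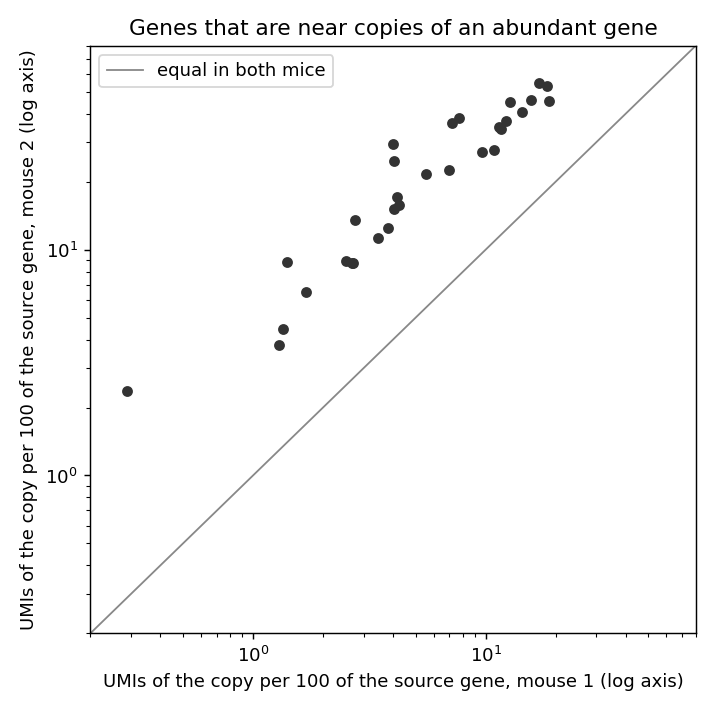
UMIs of each near-copy gene per 100 UMIs of its source gene in mouse 1 (horizontal) and mouse 2 (vertical), log scales, with a grey line of equality. Shown are only the near copies among genes picked for being higher in mouse 2. That every point lies above the line follows largely from this choice. The copies' median log2 CPM ratio of mouse 2 to mouse 1, which is not the measure plotted, is 1.83.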

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

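All tests of the larger shares of neutrophils, B cells and classical monocytes in mouse 2 were chosen after the result was seen, as were the comparison of near-copy genes with 400 other genes and that of single club markers; the other tests of the club and ciliated cells and of the near copies were written down first. The report's comparisons left out 4 clusters that nevertheless carried clear signals. They were a cycling cluster of 143 cells, 1 of 49 cells with AT2 and some neutrophil markers, 74 cells with club and ciliated markers, and 10 cells with AT2 and endothelial markers. At resolution 2, a cluster of 12 and 17 cells in mice 1 and 2 carried AT2 and neutrophil markers. Another of 14 and 6 cells carried AT2 markers without a neutrophil signal among its best 3, so not all of the 49 cells need carry both. They stand out as a signal in cells that no comparison used.

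The 74 club and ciliated cells (50 in mouse 1, 24 in mouse 2) each expressed at least 3 markers of both classes. Chance doublets do not account for them: 0.353 were expected from the class shares, so 210 times as many were seen. Cells left attached by the digestion met the test written for them, since 0.120% of 3320 genes (4 genes: Hba-a1, Hba-a2, Sftpc and Slc25a23) lay over 2 times above both classes and 85.1% lay between them. Their median UMIs (22047 and 24838) were 1.31 and 1.34 times the sum of the 2 class medians. Single club markers did not all follow such a mixture: Scgb3a1 stood at 487 CPM against 6494 in club cells and Bpifa1 at 171 against 1827, while Scgb1a1 kept 414050 of 549262, and Cyp2f2 (6253 CPM) and Aldh1a1 (1498) lay above both classes. Whether the club cells in them were of another kind than the club class was not tested. A single cell with both programmes could also lie between the classes and stays possible, and no biological explanation was tested, since the design gives none.

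Neutrophils, B cells and classical monocytes took a larger share of mouse 2, a difference that was not tested. For neutrophils, the lower UMI minimum of mouse 2 may add to it but is not the whole cause, as their share stayed 8.92-fold larger in mouse 2 with 1 minimum for both mice. Fewer recovered epithelial and stromal cells is not the whole cause for neutrophils either, as their share of immune cells alone was 15.8-fold larger. Both verdicts rested on neutrophils alone and do not cover B cells or classical monocytes. More blood left in the vessels of mouse 2 could be neither held nor dropped: per endothelial cell, neutrophils were 26.7-fold, platelets 4.59-fold, B cells 3.43-fold, classical monocytes 3.29-fold and NK cells 1.91-fold more frequent, but T cells 1.01-fold and non-classical monocytes 1.14-fold. No biological explanation was tested, as the 2 mice belong to 1 group.

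The genes that stood at least 2-fold higher in mouse 2 in at least 3 classes were mostly near copies of ribosomal and other abundant genes. Of 43 such genes, 31 (72.1%) shared over 50% of their 31-base words with a more abundant gene, against 2 of 400 other genes (0.5%). That share lay just past the 70% written beforehand. The pattern was already described as genes resembling others when the 70% was written, so passing it is weak support. More reads of near-identical genes may have been counted at the copies in mouse 2. Source and copy were not summed, so reads moved from the source were not told apart from reads added at the copy. More RNA of the source genes is not a likely cause, since their median log2 ratio was 0.00335 (29 genes, -0.257 to 0.549) against 1.83 (1.12 to 2.67) for the copies. The copies had been picked for a log2 ratio of at least 1 in at least 3 classes, which bounds their values, while the source genes were not picked by ratio. The copies' median was 1.93 with 1 UMI minimum, but that minimum drops cells and does not equalize depth, so it cannot decide on shallower cells. Median UMIs per cell were lower in mouse 2 in NK cells (1651 and 1375 in mice 1 and 2). They were not lower in AT2 cells (3571 and 3685), alveolar macrophages (3116 and 3128) or classical monocytes (2907 and 3916). The copies were higher in mouse 2 in every class where they were counted (lowest log2 ratio 1.04), which argues against shallower cells. Why the 2 libraries would be counted differently was not tested, and no biological explanation was tested.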

How the results depend on the processing

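The equal UMI minimum and the fit of only classes with 50 cells in each mouse were chosen after the data were seen. Of the values of named genes under alternatives, 1853 were counted as unchanged and 26 lost their call with the same sign. Of the 26, 25 were with DESeq2 and 1 (Lpl) without the block, and no call reversed. The 1853 include 157 values for each mouse left out. These were compared by sign alone, with no threshold, and the naming rule had required the same sign in each mouse for most of them. Counts of genes stayed within 1.5 times in 153 cases and moved further in 7: AT2 cells with DESeq2 (1219 genes higher, 1848 in the report), monocytes without the block (254 and 328 genes, against 460 and 506; listed genes higher in classical monocytes 20, against 34), listed genes higher in classical monocytes with DESeq2 (19), and genes higher in classical monocytes with only classes of 50 cells (805 genes, with 579 higher in non-classical monocytes, and 53 listed genes). Which direction of a comparison held more calls changed with the setting in all 4 comparisons. The mouse block, whose pairing comes from the same mouse, changed no other call of a named gene. Without it, 3 further lists passed camera: growth factors and receptors in alveolar versus interstitial macrophages (0.0382), and Wnt ligands and secretion (0.0469) and TGF-beta and BMP signalling (0.0375) in endothelial cells versus fibroblasts. With an estimated correlation the lists past the threshold fell from 10 to 3 in macrophages, from 5 to 4 in AT2 and AT1 cells, from 6 to 0 in monocytes and from 6 to 1 in endothelial cells and fibroblasts. The cause of these changes was not tested. DESeq2 size factors moved the median log2 fold change of all genes from 0.14 to -0.01 in AT2 and AT1 cells and from 0.05 to -0.07 in endothelial cells and fibroblasts. The largest shift of a named fold change was Cd36 in AT2 and AT1 cells, log2 7.57 to 12.61 with RNA from other cells subtracted, followed by Map3k11 in endothelial cells and fibroblasts, log2 8.87 to 4.03 with doublets kept. Leaving out a mouse allows no test; of the lists past camera, 1 had a median of unlike sign in the 2 mice, complement and Fc receptors in endothelial cells and fibroblasts (0.45 without replicate 2 and -1.02 without replicate 1). The same held for 6 lists that had not passed, among them senescence genes in AT2 and AT1 cells (-0.54 without replicate 1 and 0.31 without replicate 2). With an equal UMI minimum, mesothelial cells (mean 0.171%) and non-classical monocytes (4.07%) moved past the spread of the 2 mice; the mean neutrophil share fell from 3.77% to 1.72%, and to 1.39% with the stricter filter, within a wide spread. Fold changes of named genes lay over 1.5 times apart in the 2 mice for 68 of 157, most for Ccnd1 in endothelial cells and fibroblasts. Resolution 0.5 and listed genes in the clustering gave values for 16 and 18 of 24 classes. At the depth of these 2 mice and the trend of spread of the fit, 2-fold changes were recovered in 35 to 59 of 100 simulated genes. These genes held at least 100 UMIs in the 2 classes. Depth was not varied, so its part in the missed changes was not separated from the number of mice.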

Other observations

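No hypothesis was tested in this part. Mature dendritic cells, a small class of 30 and 20 cells in the 2 mice, held the highest level of several cholesterol and presentation genes of the lists. Hmgcs1 stood at 195 ± 77.6 CPM there (mean ± SD, n = 2), with AT2 cells next at 107, and the immunoproteasome gene Psmb8 at 973 ± 242 CPM. NK cells were highest for Itgb2 (619 ± 108 CPM) and Ccnd3 (455 ± 24 CPM). Plasmacytoid dendritic cells were highest for the protease Ctsh (1233 ± 80.5 CPM, AT2 cells next at 967) and Ccnd1 (489 ± 30.4 CPM). For Ctsh this order depended on the scale. TMM factors were 1.34 and 1.16 in plasmacytoid dendritic cells and 0.747 and 0.781 in AT2 cells, and TMM-scaled levels would put AT2 cells above. Interstitial macrophages were highest for the lysosomal genes Ctsc (1158 ± 170 CPM), Lgmn (892 ± 41.4 CPM) and Cd63 (857 ± 86.7 CPM) and for the Fc receptor Fcgr3 (741 ± 57.0 CPM).

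Cdkn1a stood at 961 ± 371 CPM in endothelial cells and Cdkn2b at 424 ± 63.8 CPM in AT1 cells, each the highest class. Hspa8 was highest in classical monocytes (1942 ± 286 CPM). The lung was digested before cells were caught, and levels of stress genes such as Hspa8 and Jun in the intact lung were not measured.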
